A study of Cucumis sativus with 12 samples.

How the data were processed

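Leaves of 21-day-old Cucumis sativus were sampled in 12 libraries, 3 in each of 4 groups, which the labels give as untreated, 100 mM NaCl, BC56, and BC56 with 100 mM NaCl. Per the labels' protocols, mRNA was purified with oligo(dT) beads from RNA with an integrity number above 7, made into libraries with a dUTP second strand and unique molecular identifiers, and sequenced as 2 x 150 bp pairs on an Illumina NovaSeq. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2 and edgeR without giving their roles. The use of the strand in counting and the treatment of reads that match several genes are not given in the sources used here.

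The deposited table holds an FPKM value and an estimated count for each of 20698 genes in each library, per the file headers. The deposited estimated counts are whole numbers and were not scaled between libraries. Of 24077 counts between 1 and 23, 38.0% were multiples of 4, where an even spread gives 21.7%; how the counts were made is not stated, and the number that a read pair added was not tested. All 20698 genes were found in the RefSeq gene table of Cucumber_9930_V3, 20673 with the same start, and 13980 had a product name. No column was left without a sample.

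The tests were written before the data were examined: limma on log2(FPKM + 1), or edgeR's quasi-likelihood test instead if the table also held raw read counts. The deposited counts are estimated counts, and whether they are raw read counts is not stated. Counts were tested with edgeR 4.0.16 under R 4.3.3 (filterByExpr, TMM factors of 0.954 to 1.03, 1 fit with 4 group means and 8 residual degrees of freedom), which left 18529 genes. The common biological coefficient of variation was 0.0899, and 0.0426 on counts divided by 4. If a read pair enters several times, the counts overstate the information in the reads; the dispersion was estimated from the replicates on the same scale. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, with no limit on the fold change. The comparisons were salt minus control, BC56 minus control, BC56_salt minus salt, BC56_salt minus BC56, and the interaction, which is the fourth less the first.

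Gene lists were fixed before the data were examined by patterns in product names, 39 in number, of which 38 had at least 5 tested members; a list of genes encoded in plastids and mitochondria matched 0 genes. Each list was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the 38 lists of a comparison, and again with an estimated correlation. Members were counted as called over all genes and also with p-values adjusted over the list alone. The genes named were chosen by a rule set in advance: among called genes with a name, a mean FPKM of at least 5 in the higher group and no overlap between the groups' libraries, the 5 with the greatest rise and the 5 with the greatest fall. To these the rule added 1 or 2 called members with the smallest p from each list with at least 3 called members, up to 30 genes per comparison. A gene named in 1 comparison was allowed in the others.

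The share of genes whose change from salt to BC56_salt opposed that from control to salt was set beside 20 simulations without an effect of BC56 under salt, and the slope between the salt effects beside 20 simulations with the same effect in both backgrounds. Random lists for comparison numbered 10000, drawn from the 100 nearest genes in the matched property. The fits were tested on simulated data drawn from the means of the real libraries for salt minus control (18246 genes). Of 100 genes changed by a log2 of 1, 82 were recovered, and of 100 changed by 0.5, 74, with 14 false calls among 170. A first rule, that 90% of the genes changed by a log2 of 1 be recovered, was missed; the genes missed had low counts, and after that result was seen the rule was replaced by recovery at 400 counts or more (73 of 73, and 73 of 80 for a log2 of 0.5), false calls and bias. Below 400 counts, 9 of 27 and 1 of 20 were recovered. A simulated list of 40 genes shifted by 0.3 was called, and 0 of 38 other lists were. Replicate numbers were checked for pairing: 0 of 18 pairs of libraries with the same number had a correlation of residuals above 0.1 (-0.199 to 0.0714), so libraries were not paired.

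Alternatives were these settings: limma on log2(FPKM) with pseudocounts of 0.1 and 5, no filter on low counts, a mean FPKM of at least 5, median-ratio scaling, quantile normalization, a replicate block, limma without trend, robust dispersion, only the groups of a comparison, DESeq2 1.42.0, a log2 change of at least 1, and each of the 12 libraries left out. Limma on log2(FPKM + 1) with genes of a mean FPKM of at least 1, the test planned for a table without raw read counts, was a further setting. Its use beside edgeR, and counts divided by 4, were chosen after seeing the data. The settings in limma, quantile normalization among them, changed the input, scaling, filter (15129 genes tested) and test together, so that a difference there is not that of 1 choice. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.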

Results

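Leaf mRNA of 21-day-old cucumber plants (Cucumis sativus) was sequenced in 12 libraries that formed 4 groups of 3. The plants were untreated (control), given 100 mM NaCl (salt), given a treatment with the code name BC56 (BC56), or given both (BC56_salt). The labels did not say what BC56 is, and the series title speaks of plant growth-promoting rhizobacteria, bacteria that live at the root and favour plant growth, and of systemic tolerance in the shoot. Total estimated counts per library ran from 63.3 M to 74.3 M (M, 1e6) over 20698 genes, with means of 69.9 ± 3.69 M in control, 73.4 ± 0.372 M in salt, 67.2 ± 3.59 M in BC56 and 72.8 ± 1.27 M in BC56_salt (SD, n = 3). How many counts a read pair added was not tested; at 4 counts each, these totals would be 15.8 M to 18.6 M pairs. Levels below are FPKM as deposited (mean ± SD, n = 3 libraries per group), and changes are log2 fold changes of the counts ± their standard error, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 18529 genes tested. Positions are on the Cucumber_9930_V3 assembly and span the whole annotated gene. The labels did not say whether replicates came from separate plants, so the p-values measure only the spread between these libraries.

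The 4 groups lay apart on the first principal components over 13568 genes, which held 48.5%, 27.8% and 12.1% of the variance. The input was log2 counts scaled by library size and TMM factor. On the first component the salt libraries stood at 34.8 to 39.7, BC56_salt at 1.60 to 2.18, control at -16.2 to -15.8 and BC56 at -23.9 to -22.8. Replicates of 1 group had Spearman correlations across genes of 0.995 to 0.996. On counts divided by 4, chi-square values per degree of freedom between them were 1.80 to 4.15, so that no library was a copy of another replicate. These values exceed counting noise if a read pair adds 4 counts, which was not tested. The Rubisco small subunit gene with the symbol RBCS held 2.74% ± 0.0520 of the counts in control, 2.82% ± 0.0936 in salt, 3.31% ± 0.0351 in BC56 and 2.82% ± 0.0627 in BC56_salt (SD, n = 3).

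The first comparison asked what 100 mM NaCl did to the leaf without BC56. Asparagine synthetase (LOC101214250, chromosome 6, 12057728 to 12062448), which makes the nitrogen transport compound asparagine, fell from 94.7 ± 2.81 to 3.14 ± 1.11 FPKM, a log2 change of -4.90 ± 0.14 (adjusted p = 4.65e-14). Inositol oxygenase 2 (LOC101202978, chromosome 1, 25333393 to 25335982), which opens the ring of myo-inositol, fell from 143 ± 7.56 to 3.78 ± 1.95 FPKM (-5.23 ± 0.19, adjusted p = 1.33e-12). The F-box protein gene PP2-B12 (LOC101220101, chromosome 1, 24171357 to 24173311) rose from 62.7 ± 3.29 to 1249.8 ± 133 FPKM (4.33 ± 0.15, adjusted p = 1.06e-12). A pair of heat shock protein 70 chaperone genes rose together, LOC101215599 (chromosome 4, 14570942 to 14573798) from 63.6 ± 2.08 to 483 ± 17.8 FPKM (2.94 ± 0.04) and LOC101210925 (chromosome 5, 21612425 to 21615201) from 26.5 ± 0.832 to 207 ± 7.50 FPKM (2.98 ± 0.04). Salt changed 9445 genes, of which 4899 rose and 4546 fell, and 1413 of them changed by a log2 of 1 or more (n = 3 against 3). In 59.1% of the genes tested the 3 salt libraries did not overlap the 3 control libraries in deposited FPKM, where chance gives 10%.

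Among the further genes with the greatest rises were a glucosyltransferase, LOC101220652 (3.93 ± 0.13), and a pair of cytochrome P450 genes on chromosome 5, LOC116401644 (3.62 ± 0.07) and LOC101215503 (3.23 ± 0.10). An anthocyanidin glucosyltransferase gene, LOC101222215, rose from 13.4 ± 0.487 to 125 ± 5.28 FPKM (3.22 ± 0.07). Further falls were those of a WAT1-related transporter, LOC101221252 (-4.18 ± 0.10), the auxin-induced AUX22-like gene LOC101210711 (6.83 ± 1.13 to 0.415 ± 0.256 FPKM) and the chloroplast 13-lipoxygenase LOC101216566 (-3.97 ± 0.16), an enzyme at the start of jasmonate synthesis. Among the 5 greatest rises and 5 greatest falls by the naming rule, the largest adjusted p was 6.24e-08.

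Of 38 gene lists fixed before the data were examined, 4 passed the camera test for salt. Heat shock factors and heat shock proteins rose in 28 of 62 members and fell in 9, with the same counts adjusted over the list alone, and 25 members did not pass. Their median was 0.26 (camera adjusted p = 2.96e-08, adjusted p = 0.0145 with an estimated correlation). Photosystem and antenna proteins, which harvest light, rose in 29 of 41 members and fell in 5 (30 and 5 adjusted over the list alone), with 7 not passing. Their median was 0.28 (camera adjusted p = 1.84e-07, adjusted p = 0.579 with an estimated correlation). The LHCII type I gene LOC101221671 rose from 793 ± 20.5 to 2296 ± 20.5 FPKM (1.55 ± 0.03), and the P4 antenna gene LOC101222701 from 608 ± 11.9 to 1009 ± 19.5 FPKM (0.74 ± 0.03). Cytosolic ribosomal protein genes fell in 109 of 163 members and rose in 9 (111 and 9 adjusted over the list alone), with 45 not passing. Their median was -0.17 (camera adjusted p = 3.55e-04, adjusted p = 0.753 with an estimated correlation). L3-2 (LOC101221039) had -1.04 ± 0.04 and S7-1-like (LOC101214141) -0.31 ± 0.03. Ethylene synthesis and signalling genes fell in 13 of 27 members and rose in 5, with the same counts adjusted over the list alone, and 9 did not pass. Their median was -0.24 (camera adjusted p = 0.0289, adjusted p = 0.527 with an estimated correlation). The fallen members included EIN3-binding F-box protein 1 (LOC101220113; -1.07 ± 0.04), which marks the ethylene factor EIN3 for breakdown, and the ethylene receptor CS-ETR2 (-0.79 ± 0.04). The ethylene call was lost in the limma fits on FPKM and among genes with a mean FPKM of at least 5.

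The other 34 lists did not pass (camera adjusted p = 0.109 to 0.964), and several had members that moved both ways. Sodium, potassium and proton transport genes rose in 21 of 73 members and fell in 21, also adjusted over the list alone (median 0.02, camera adjusted p = 0.795). Abscisic acid genes rose in 18 of 51 and fell in 16, or 17 adjusted over the list alone (adjusted p = 0.816). Abscisic acid 8'-hydroxylase 3 (LOC101206277), which breaks the hormone down, rose by 2.22 ± 0.05. Aquaporin genes, which encode water channels, fell in 12 of 25 and rose in 4, with the same counts adjusted over the list alone (adjusted p = 0.109). The gene with the symbol PIP1-3 had -1.93 ± 0.06, whereas the gene with the symbol PIP1-2, a PIP1-4-like aquaporin, had 0.54 ± 0.03. The osmolyte list took in enzymes of synthesis and also of breakdown, such as inositol oxygenase. Its genes rose in 13 of 27 and fell in 6, also adjusted over the list alone (adjusted p = 0.239). LEA and dehydrin genes rose in 1 and fell in 1 of 10, likewise on both counts (adjusted p = 0.964). The clock gene APRR7 (LOC101222491) rose from 29.3 ± 1.31 to 136 ± 10.3 FPKM (2.23 ± 0.05), in a clock list with 11 risen and 5 fallen of 21, or 11 and 6 adjusted over the list alone (adjusted p = 0.109). Phenylpropanoid and flavonoid genes rose in 37 of 96 and fell in 15, or 16 adjusted over the list alone (adjusted p = 0.118), and trans-cinnamate 4-monooxygenase (LOC101221846), an early enzyme of that route, was among those that fell (-1.48 ± 0.04). WRKY41 (LOC101204004; -1.71 ± 0.08) and WRKY45 (LOC101212622; -1.51 ± 0.09) fell in a WRKY list with 24 fallen and 15 risen of 55, also adjusted over the list alone (adjusted p = 0.239).

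**Figure D1:**
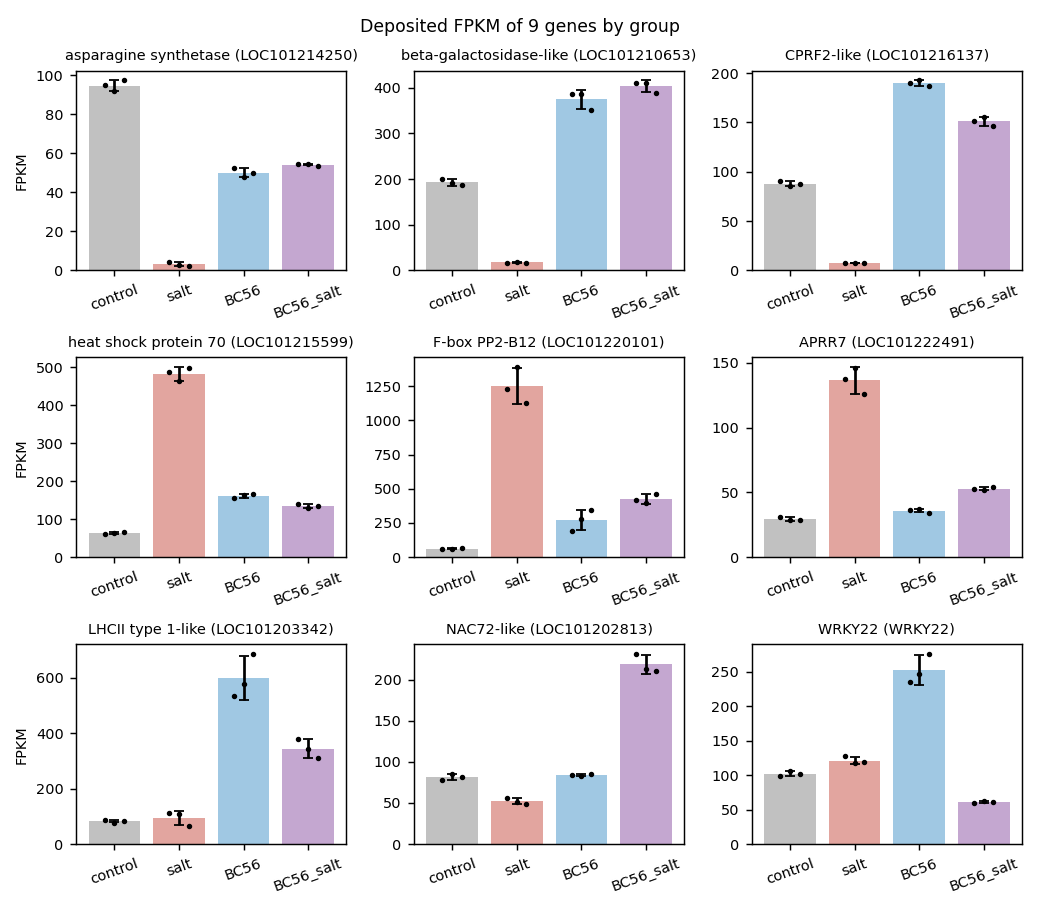
Deposited FPKM (y axis, from 0, a separate scale in each panel) of 9 genes in the 4 groups (x axis), with bars for means, error bars for SDs and points for the 3 libraries of a group. Asparagine synthetase, beta-galactosidase-like and CPRF2-like were lowest in salt, HSP70, PP2-B12 and APRR7 highest in salt, the LHCII type 1-like gene highest in BC56, NAC72-like highest in BC56_salt, and WRKY22 highest in BC56 (252 ± 21.2 FPKM) and lowest in BC56_salt (60.7 ± 1.46 FPKM).

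The next comparison asked what BC56 did without salt. Genes of light harvesting rose throughout: all 41 members of the photosystem and antenna list rose, also adjusted over the list alone, with a median log2 change of 0.85 (camera adjusted p = 2.91e-102, adjusted p = 0.0127 with an estimated correlation). The LHCII type 1-like gene LOC101203342 (chromosome 3, 27304239 to 27305226) rose from 82.8 ± 4.61 to 600.0 ± 78.2 FPKM (2.97 ± 0.15, adjusted p = 1.64e-10), and its relative LOC101211276 (chromosome 1, 19549770 to 19551320) from 5.32 ± 1.07 to 42.0 ± 4.86 FPKM (3.09 ± 0.17). All 14 Calvin cycle genes, which fix carbon, rose as well, also adjusted over the list alone. Their median was 0.48 (camera adjusted p = 7.73e-14, adjusted p = 0.0733 with an estimated correlation). SBPASE (chromosome 5, 5492201 to 5494540) rose from 544 ± 5.84 to 802 ± 3.64 FPKM (0.67 ± 0.03). Cytosolic ribosomal protein genes moved the other way: 134 of 163 fell, 0 rose and 29 did not pass, with 141 fallen adjusted over the list alone. Their median was -0.25 (camera adjusted p = 1.45e-16, adjusted p = 0.225 with an estimated correlation). BC56 changed 7461 genes, 4047 up and 3414 down, of which 709 changed by a log2 of 1 or more (n = 3 against 3). In deposited FPKM, without scaling, the libraries of the groups did not overlap in 55.4% of genes, where chance gives 10%. Of these 10270 genes, 6510 were called. Such shares, here and in the other comparisons, include any shift of the FPKM of a whole group. On log2(FPKM + 1) as deposited, limma called 8307 genes with 2667 up and 5640 down, so that 32.1% rose in place of 54.2%; the median of all genes there was -0.10, and -0.11 with a pseudocount of 0.1.

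Of the 38 lists, 12 passed for BC56 without salt, and 5 of these also with an estimated correlation. Chlorophyll synthesis genes rose in 16 of 23 members and fell in 1, with the same counts adjusted over the list alone. Their median was 0.28 (camera adjusted p = 5.63e-09, adjusted p = 0.0497 with an estimated correlation). Protochlorophyllide reductase (symbol NPR), which makes chlorophyllide in the light, rose from 193 ± 4.57 to 381 ± 8.30 FPKM (1.09 ± 0.03). Further members of the photosystem list with large rises were the antenna genes LOC101218675 (2.32 ± 0.23) and LOC101212963 (1.28 ± 0.03). Outside these lists, the BTB/TAZ domain gene LOC101217572 rose from 67.4 ± 0.490 to 343 ± 14.1 FPKM (2.46 ± 0.04), and the GAST1 gene LOC101222161 had 2.38 ± 0.22. Circadian clock genes rose in 18 of 21 members, also adjusted over the list alone, and 3 did not pass. Their median was 0.39 (camera adjusted p = 3.12e-06, adjusted p = 0.0354 with an estimated correlation), with REVEILLE 6 (LOC101212382) at 0.80 ± 0.04, GIGANTEA (LOC101216952) at 0.48 ± 0.03 and APRR7 (LOC101222491) at 0.41 ± 0.05. Of the ribosomal protein genes, L3-2 (LOC101221039) had -0.62 ± 0.04 and S7-1-like (LOC101214141) -0.34 ± 0.03.

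Class III peroxidases, secreted enzymes that use hydrogen peroxide, fell in 10 of 39 members and rose in 4, with the same counts adjusted over the list alone. Their median was -0.18 (camera adjusted p = 2.28e-05, adjusted p = 0.0354 with an estimated correlation), though the call was lost in 3 of the limma fits on FPKM. This median was -0.81 at a mean FPKM of at least 5 and -0.06 without control replicate 2. Peroxidase 2-like (LOC101217781) fell from 54.1 ± 0.432 to 9.95 ± 0.616 FPKM (-2.34 ± 0.06), and peroxidase 21-like (LOC101215428) from 395 ± 14.1 to 116 ± 1.64 FPKM (-1.66 ± 0.06). The osmolyte list was drawn by patterns that also took in the breakdown enzymes inositol oxygenase and proline dehydrogenase, so it does not measure synthesis alone. Its genes rose in 13 of 27 and fell in 4, also adjusted over the list alone. Their median was 0.39 (camera adjusted p = 0.00172, adjusted p = 0.0354 with an estimated correlation); a trehalose-phosphate synthase, LOC101213082, had 0.84 ± 0.04 and inositol oxygenase 2 (LOC101202978), which consumes inositol, 1.24 ± 0.15. Heat shock genes rose in 19 of 62 and fell in 7, also adjusted over the list alone. Their median was 0.11 (camera adjusted p = 0.0104, adjusted p = 0.0848 with an estimated correlation), with HSP70 LOC101215599 at 1.45 ± 0.04. Antioxidant enzyme genes rose in 31 of 75 and fell in 13, or 14 adjusted over the list alone. Their median was 0.11 (camera adjusted p = 0.0201, adjusted p = 0.189 with an estimated correlation), a call lost in the limma fits on FPKM and among genes with a mean FPKM of at least 5; a chloroplast thioredoxin-like gene, LOC101219391, had 1.06 ± 0.04. Cell cycle and histone genes fell in 36 of 140 and rose in 14, also adjusted over the list alone. Their median was -0.01 (camera adjusted p = 0.0458, adjusted p = 0.0848 with an estimated correlation), with histone H1 (LOC101219077) at -0.98 ± 0.03 and the H1-like LOC101205659 at -0.83 ± 0.04. Jasmonate genes rose in 17 of 40 and fell in 6, also adjusted over the list alone. Their median was 0.24 (camera adjusted p = 0.0487, adjusted p = 0.310 with an estimated correlation), and the lipoxygenase LOC101209041 had 1.52 ± 0.06. The cell cycle call was lost without control replicate 3, salt replicate 1, BC56 replicate 1 or BC56 replicate 3 and in 6 other settings, and the jasmonate call without salt replicates 1 or 2, BC56 replicate 2 or any 1 of the BC56_salt replicates 1, 2 and 3, and in 5 other settings.

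The remaining 26 lists did not pass (camera adjusted p = 0.0852 to 0.8004). Single members of them moved far: abscisic acid 8'-hydroxylase 3 (LOC101206277) fell by 1.62 on the log2 scale (SE 0.06) to 3.62 ± 0.286 FPKM, WRKY46 (LOC101207215) rose by 1.35 ± 0.05, chlorophyllase-1-like (LOC105434597) by 1.25 ± 0.05 and the RAV2-like repressor LOC101203784 by 1.45 ± 0.03. An ACC oxidase homolog (LOC101214319; -1.06 ± 0.04) and an inactive leucine-rich repeat receptor-like kinase (LOC101215026; -1.99 ± 0.08) fell. The respiratory burst oxidase C gene LOC101209614 had 0.95 ± 0.04 and the MAP kinase 3-like gene TIPK 0.52 ± 0.03. Further large falls were those of a glycine-rich protein gene, LOC101209541 (-2.72 ± 0.23), a protease inhibitor gene, LOC101213267 (-3.24 ± 0.62), an external NAD(P)H dehydrogenase gene, LOC101204145 (-2.40 ± 0.15), and the mitochondrial ribosomal S13 gene LOC116401621 (-2.37 ± 0.44). For LOC116401621, replicate 1 lay below replicates 2 and 3 in control (8.05 against 18.0 and 18.5 FPKM), salt (6.69 against 16.1 and 14.7) and BC56_salt (4.80 against 13.5 and 12.5). It did not lie below both in BC56 (2.49 against 4.07 and 1.42). For LOC101213267, replicate 1 lay above the others in control (23.5 against 11.8 and 11.1 FPKM) and salt (32.0 against 5.52 and 3.92). The miraculin-like gene LOC101213024 had -5.23 ± 1.24 (adjusted p = 0.00280), with 5.48 ± 8.59 FPKM in control; without control replicate 1 its change was -1.89 and its adjusted p 0.0848.

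The comparison that the series title points to set BC56_salt against salt and asked what BC56 did in plants under salt. Genes that were lowest in salt alone stood out: beta-galactosidase-like (LOC101210653, chromosome 1, 25674701 to 25680121), a cell wall sugar hydrolase, was at 17.3 ± 0.456 FPKM in salt and 404 ± 13.2 in BC56_salt (4.60 ± 0.05, adjusted p = 1.49e-19), against 193 ± 7.02 in control. The CPRF2-like transcription factor gene LOC101216137 (chromosome 1, 24929514 to 24933646) rose from 7.18 ± 0.0623 to 151 ± 4.60 FPKM (4.45 ± 0.04), asparagine synthetase (LOC101214250) from 3.14 ± 1.11 to 54.1 ± 0.363 FPKM (4.16 ± 0.13) and inositol oxygenase 2 (LOC101202978) from 3.78 ± 1.95 to 54.4 ± 4.84 FPKM (3.90 ± 0.19). Both heat shock protein 70 genes fell, LOC101215599 from 483 ± 17.8 to 135 ± 4.10 FPKM (-1.79 ± 0.04) and LOC101210925 from 207 ± 7.50 to 59.8 ± 2.20 FPKM (-1.74 ± 0.04). BC56 under salt changed 7834 genes, 3961 up and 3873 down (n = 3 against 3), and of the 877 that changed by a log2 of 1 or more, 667 rose and 210 fell. Libraries of the 2 groups did not overlap in deposited FPKM in 52.1% of genes, where chance gives 10%. On log2(FPKM + 1), limma called 7877 genes with 2959 up and 4918 down, so that 37.6% rose in place of 50.6%.

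Of the 38 lists, 6 passed for BC56 under salt, and each call was lost with an estimated correlation. Cytosolic ribosomal protein genes fell in 138 of 163 members and rose in 3, with 22 not passing (146 and 3 adjusted over the list alone). Their median was -0.24 (camera adjusted p = 4.37e-13, adjusted p = 0.422 with an estimated correlation). L13-3-like (LOC101218701) had -0.53 ± 0.04, while L3-2 (LOC101221039) was 1 of the 3 that rose (0.54 ± 0.04). Photosystem and antenna genes rose in 31 of 41 and fell in 4, or 5 adjusted over the list alone. Their median was 0.22 (camera adjusted p = 2.72e-05, adjusted p = 0.536 with an estimated correlation), with LOC101203342 at 1.93 ± 0.15 and the antenna gene LOC101214055 at 0.50 ± 0.03; photosystem II 22 kDa protein (LOC101206477), known from the dissipation of excess light, was among the 4 that fell (-0.53 ± 0.04). Heat shock genes fell in 22 of 62 and rose in 9, also adjusted over the list alone. Their median was -0.24 (camera adjusted p = 7.18e-05, adjusted p = 0.0905 with an estimated correlation). NAC transcription factor genes rose in 20 of 49 and fell in 5, also adjusted over the list alone. Their median was 0.34 (camera adjusted p = 0.0204, adjusted p = 0.206 with an estimated correlation), and in limma with a pseudocount of 5 it was 0.12. NAC72-like (LOC101202813) rose from 52.3 ± 3.52 to 218 ± 11.2 FPKM (2.12 ± 0.05) and NAC2-like (LOC101217461) had 0.59 ± 0.05. Glutathione transferase genes fell in 16 of 38 and rose in 4, or 5 adjusted over the list alone. Their median was -0.18 (camera adjusted p = 0.0294, adjusted p = 0.461 with an estimated correlation), with LOC101219529 at -0.73 ± 0.04 and LOC101217418 at 1.33 ± 0.05. The glutathione transferase call was lost in 5 limma fits on FPKM and without BC56_salt replicate 1. The sixth list was that of phloem markers, given with the other cell type markers.

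The other 32 lists did not pass (camera adjusted p = 0.0673 to 0.936). Genes of these lists with small p-values included MAP kinase kinase 6 (LOC101218848; 2.25 ± 0.11), the chloride channel gene CLCA (1.63 ± 0.05), the lipoxygenase LOC101216318 (2.18 ± 0.10) and glutamate dehydrogenase 2 (LOC101202786; 0.95 ± 0.05), which all rose. The auxin-repressed 12.5 kDa protein gene LOC101202889 reached 1509 ± 71.5 FPKM (1.10 ± 0.05) and the auxin-binding protein gene LOC101203480 129 ± 7.22 FPKM (1.10 ± 0.05), in an auxin list with 34 risen and 12 fallen of 101, or 35 and 12 adjusted over the list alone (adjusted p = 0.0673). This list passed upwards in 9 alternatives: the 5 limma fits, a mean FPKM of at least 5, and the fits without salt replicate 1, salt replicate 2 or BC56_salt replicate 2 (adjusted p = 0.0126 to 0.0432). The jasmonate list (adjusted p = 0.0695) passed upwards in 9 as well, those of the auxin list with only the groups of the comparison in place of a mean FPKM of at least 5. With medians above 0, the anion transport and calcium signalling lists passed in the 5 limma fits and at a mean FPKM of at least 5 (adjusted p = 0.0212 to 0.0439). The cell wall list passed in the 5 limma fits (0.0177 to 0.0318), and the clock list in those without quantile normalization (0.0312 to 0.0346). Nitrogen assimilation passed without salt replicate 1 or 2 and on counts divided by 4, and the osmolyte list at a mean FPKM of at least 5 (median -0.12). Gibberellin 3-beta-dioxygenase 1 (LOC101223012), which makes active gibberellins, fell from 110.0 ± 6.12 to 32.7 ± 1.25 FPKM (-1.69 ± 0.05), and 12-oxophytodienoate reductase 1 (LOC101203714), a jasmonate enzyme, had -0.71 ± 0.03. The plastid glucose 6-phosphate translocator gene LOC101216621 (-2.72 ± 0.14) and the cytochrome P450 gene LOC101215503 (-2.48 ± 0.10) had the greatest falls by the naming rule, and the inactive beta-amylase 4 gene LOC101210545 had a rise of 4.06 ± 0.18.

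The salt effect in plants given BC56 was read from BC56_salt minus BC56. Here salt lowered genes of light harvesting and carbon fixation: 38 of 41 photosystem and antenna genes fell and 0 rose, or 38 and 1 adjusted over the list alone. Their median was -0.38 (camera adjusted p = 4.49e-30, adjusted p = 0.0754 with an estimated correlation). Of 14 Calvin cycle genes, 10 fell and 1 rose, or 11 and 1 adjusted over the list alone. Their median was -0.26 (camera adjusted p = 6.07e-07, adjusted p = 0.198 with an estimated correlation). Photosystem II 22 kDa protein (LOC101206477) fell from 462 ± 15.7 to 248 ± 1.56 FPKM (-0.94 ± 0.04), and Rubisco activase (LOC101217766, chromosome 5, 4993764 to 4996023), which keeps the carbon-fixing enzyme active, from 7311 ± 149.8 to 4475 ± 127 FPKM (-0.75 ± 0.04). Abscisic acid 8'-hydroxylase 3 (LOC101206277) rose from 3.62 ± 0.286 to 26.4 ± 0.824 FPKM (2.82 ± 0.06, adjusted p = 2.46e-14), and peroxidase 21-like (LOC101215428) from 116 ± 1.64 to 708 ± 34.5 FPKM (2.57 ± 0.06). WRKY22 (chromosome 3, 28528103 to 28529064), a defence transcription factor, fell from 252 ± 21.2 to 60.7 ± 1.46 FPKM (-2.10 ± 0.05). Salt changed 6277 genes in BC56 plants, 3115 up and 3162 down, 628 of them by a log2 of 1 or more (n = 3 against 3). In deposited FPKM, 46.9% of genes had libraries that did not overlap, where chance gives 10%. On log2(FPKM + 1), limma called 6486 genes with 3920 up and 2566 down, so that 60.4% rose in place of 49.6%.

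Of the 38 lists, 10 passed for salt in BC56 plants, each call being lost with an estimated correlation. Ribosomal protein genes fell in 105 of 163 and rose in 3, or 128 called in either direction adjusted over the list alone. Their median was -0.15 (camera adjusted p = 1.89e-07, adjusted p = 0.455 with an estimated correlation), with L32-1-like (LOC101208924) at -0.28 ± 0.04 and L13-3-like (LOC101218701) at -0.18 ± 0.04. Chlorophyll synthesis genes fell in 17 of 23 and rose in 3, also adjusted over the list alone. Their median was -0.21 (camera adjusted p = 2.09e-05, adjusted p = 0.128 with an estimated correlation), with uroporphyrinogen-III C-methyltransferase (LOC101222061), which leads to siroheme, at -0.75 ± 0.03 and protochlorophyllide reductase (NPR) at -0.17 ± 0.03. WRKY genes fell in 21 of 55 and rose in 8, or 23 and 9 adjusted over the list alone. Their median was -0.21 (camera adjusted p = 8.16e-05, adjusted p = 0.0754 with an estimated correlation). Class III peroxidases rose in 8 of 39 and fell in 3, also adjusted over the list alone. Their median was 0.12 (camera adjusted p = 8.69e-04, adjusted p = 0.0754 with an estimated correlation). This call was lost in 5 limma fits on FPKM with medians above 0, and kept with no filter on low counts (median -0.05), without BC56 replicate 3 (-0.02) and without BC56_salt replicate 3 (nearly 0). NAC genes rose in 15 of 49 and fell in 3, also adjusted over the list alone. Their median was 0.20 (camera adjusted p = 8.84e-04, adjusted p = 0.0754 with an estimated correlation), with NAC72-like (LOC101202813) at 1.33 ± 0.05. Antioxidant genes fell in 22 of 75 and rose in 7, or 24 and 7 adjusted over the list alone. Their median was -0.08 (camera adjusted p = 0.00996, adjusted p = 0.170 with an estimated correlation), with chloroplast copper-zinc superoxide dismutase (LOC101221780) at -0.74 ± 0.04; the call was lost with quantile normalization. Abscisic acid genes rose in 22 of 51 and fell in 13, or 23 and 16 adjusted over the list alone. Their median was 0.10 (camera adjusted p = 0.0235, adjusted p = 0.0754 with an estimated correlation). AP2/ERF genes rose in 30 of 101 and fell in 10, or 34 and 10 adjusted over the list alone. Their median was 0.17 (camera adjusted p = 0.0369, adjusted p = 0.0754 with an estimated correlation), with ERF106 (LOC101214089) at 1.24 ± 0.05. The abscisic acid call was lost in 6 alternatives, and the AP2/ERF call in 6, among them the fits without BC56 replicate 2 and without BC56_salt replicate 3.

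The other 28 lists did not pass (camera adjusted p = 0.0543 to 0.978). Further large rises in BC56 plants were those of the cytochrome P450 CYP72A219-like gene (symbol CYP; 2.94 ± 0.06), a flavonol synthase-like gene (LOC101221281; 2.60 ± 0.07), a kirola-like gene (LOC101212668; 2.59 ± 0.24) and threonine aldolase 1 (LOC101205504; 2.57 ± 0.10). The greatest falls by the naming rule were those of alpha carbonic anhydrase 7-like (LOC101221989; -3.66 ± 0.12), MYB108-like (LOC101206042; -3.13 ± 0.23), a cupredoxin (LOC101203127; -3.02 ± 0.48), inositol oxygenase 2 (LOC101202978; -2.57 ± 0.15) and a cysteine-rich receptor-like kinase (LOC101221965; -2.52 ± 0.21). Defence genes that fell included EDS1L (LOC101214385; -1.09 ± 0.04), in a salicylic acid list with 3 fallen and 1 risen of 15, also adjusted over the list alone (adjusted p = 0.173), and an LRR receptor-like kinase (LOC101206211; -1.44 ± 0.04). ACC oxidase 5 (LOC101204347), the last enzyme of ethylene synthesis, had -1.02 ± 0.03, a pectinesterase (LOC101207996) had -1.29 ± 0.06 and a fasciclin-like arabinogalactan protein (LOC101206457) -1.40 ± 0.11. Among the anion transport genes 19 of 64 rose and 8 fell, or 19 and 9 adjusted over the list alone (adjusted p = 0.224), and among those of sodium, potassium and proton transport 19 of 73 rose and 12 fell, or 19 and 15 adjusted over the list alone (adjusted p = 0.413). Their members that rose included NPF5.1 (LOC101211524; 0.99 ± 0.05) and potassium transporter 10-like (LOC101217915; 0.54 ± 0.03), and cyclic nucleotide-gated channel 2, of the calcium signalling list, rose too (LOC101203560; 0.71 ± 0.03). Gibberellin 3-beta-dioxygenase 1 (LOC101223012) rose here too (1.77 ± 0.06), as it did with salt alone (2.70 ± 0.06).

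Markers of other cell types were followed in each comparison beside the photosystem genes, which are those of mesophyll. The phloem list rose in 11 of 25 members and fell in 2 in BC56 minus control, or 12 and 2 adjusted over the list alone. Their median was 0.24 (camera adjusted p = 0.0202, adjusted p = 0.142 with an estimated correlation). In BC56_salt minus salt 9 members rose and 2 fell, or 10 and 3 adjusted over the list alone. Their median was 0.27 (camera adjusted p = 0.0102, adjusted p = 0.206 with an estimated correlation). Of its 25 members, 14 were F-box proteins with a domain of phloem protein 2, such as PP2-A13 (LOC101207304, 1.19 ± 0.03 under salt) and PP2-A14 (LOC101208233, 1.29 ± 0.05). These are parts of ubiquitin ligases and not phloem proteins themselves. In BC56 minus control 6 of these 14 rose and 2 fell, against 5 and 0 of the other 11. In BC56_salt minus salt 3 of the 14 rose and 2 fell, against 6 and 0 of the other 11. The phloem call under salt was lost with quantile normalization. It did not pass in salt minus control (camera adjusted p = 0.693), BC56_salt minus BC56 (0.893) or the interaction (0.640). Epidermis and cuticle markers (89 members) passed in no comparison, with camera adjusted p from 0.501 to 0.931, nor did xylem markers (28 members, 0.102 to 0.812) or guard cell markers (11 members, 0.575 to 0.917). The xylem list, with a median of -0.21 in BC56_salt minus BC56, passed downwards there in 9 alternatives: the 5 limma fits, a mean FPKM of at least 5 (median -0.35, adjusted p = 0.0158), only the groups of the comparison, and the fits without BC56 replicate 1 or BC56_salt replicate 1. In the interaction it passed at a mean FPKM of at least 5 (median -0.44, adjusted p = 0.0427).

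Whether the salt effect differed between plants with and without BC56 was tested as an interaction, the change in BC56_salt minus BC56 less that in salt minus control. Among called genes with a name and a mean FPKM of at least 5 in the highest group, asparagine synthetase (LOC101214250) had the greatest positive interaction (4.97 ± 0.17, adjusted p = 2.49e-12). Salt changed it by a log2 of -4.90 without BC56, while with BC56 it stood at 50.1 ± 2.49 FPKM without and 54.1 ± 0.363 FPKM with salt, a difference of 0.07 ± 0.11 that did not pass (adjusted p = 0.683). Beta-galactosidase-like (LOC101210653) fell from 193 to 17.3 FPKM with salt alone and stood at 375 and 404 FPKM in BC56 and BC56_salt (interaction 3.53 ± 0.06). The opposite held for the HSP70 genes LOC101215599 (-3.24 ± 0.05) and LOC101210925 (-3.32 ± 0.06), which salt raised by 2.94 and 2.98 without BC56 and changed by -0.31 and -0.34 with it. The interaction was called for 5963 genes, 2830 positive and 3133 negative, 984 of them with a log2 of 1 or more (n = 3 per group). On log2(FPKM + 1), limma called 5963 genes with 3415 positive and 2548 negative, so that 57.3% were positive in place of 47.5%.

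Of the 38 lists, 11 passed the interaction test, and with an estimated correlation only the heat shock list did. Heat shock genes were negative in 24 of 62 members and positive in 3, also adjusted over the list alone. Their median was -0.31 (camera adjusted p = 3.17e-10, adjusted p = 0.00765 with an estimated correlation). Photosystem and antenna genes were negative in 38 of 41 and positive in 0, or 39 and 0 adjusted over the list alone. Their median was -0.67 (camera adjusted p = 3.59e-45, adjusted p = 0.0642 with an estimated correlation), with LOC101221671 at -1.47 ± 0.04. Calvin cycle genes were negative in 13 of 14 and positive in 0, also adjusted over the list alone. Their median was -0.44 (camera adjusted p = 8.13e-09, adjusted p = 0.178 with an estimated correlation), with SBPASE at -0.68 ± 0.04. Chlorophyll synthesis genes were negative in 11 of 23 and positive in 0, or 12 and 0 adjusted over the list alone. Their median was -0.15 (camera adjusted p = 2.12e-05, adjusted p = 0.152 with an estimated correlation), with NPR at -0.87 ± 0.04. Class III peroxidases were positive in 14 of 39 and negative in 2, or 15 and 3 adjusted over the list alone. Their median was 0.23 (camera adjusted p = 5.77e-04, adjusted p = 0.0642 with an estimated correlation), with peroxidase 21-like (LOC101215428) at 2.08 ± 0.08. The median of this list went from 0.03 without control replicate 1 to 0.67 in limma with a pseudocount of 0.1, and the call was kept. NAC genes were positive in 14 of 49 and negative in 5, also adjusted over the list alone. Their median was 0.31 (camera adjusted p = 0.00799, adjusted p = 0.0642 with an estimated correlation), with NAC72-like (LOC101202813) at 1.96 ± 0.07; the call was lost in 4 limma fits on FPKM. Antioxidant genes were negative in 28 of 75 and positive in 10, or 32 and 10 adjusted over the list alone. Their median was -0.14 (camera adjusted p = 0.0222, adjusted p = 0.220 with an estimated correlation), with the thioredoxin-like gene CDSP32 (LOC101214005) at -0.72 ± 0.05; this call was lost with quantile normalization.

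Aquaporin genes were positive in 10 of 25 and negative in 3, also adjusted over the list alone. Their median was 0.44 (camera adjusted p = 0.0257, adjusted p = 0.310 with an estimated correlation), a call lost in the limma fits and among genes with a mean FPKM of at least 5; PIP1-3 had 1.902 ± 0.075, with 48.3 ± 2.22 FPKM in control, 12.6 ± 0.902 in salt, 40.4 ± 1.93 in BC56 and 40.9 ± 0.499 in BC56_salt. AP2/ERF genes were positive in 32 of 101 and negative in 11, also adjusted over the list alone. Their median was 0.33 (camera adjusted p = 0.0259, adjusted p = 0.0642 with an estimated correlation), although the member with the smallest p, the RAV2-like repressor LOC101203784, was negative (-2.59 ± 0.05). Auxin response genes were positive in 28 of 101 and negative in 13, or 30 and 14 adjusted over the list alone. Their median was 0.21 (camera adjusted p = 0.0449, adjusted p = 0.452 with an estimated correlation), with IAA11 (LOC101204327) at 1.69 ± 0.12. Clock genes were negative in 8 of 21 and positive in 2, or 9 and 2 adjusted over the list alone. Their median was -0.08 (camera adjusted p = 0.0481, adjusted p = 0.253 with an estimated correlation), with APRR7 (LOC101222491) at -1.72 ± 0.07. The auxin call was lost in 6 alternatives, among them the fits without control replicate 3, salt replicate 3, BC56 replicate 1 or BC56_salt replicate 1, and the clock call in 11, among them those without control replicate 2, BC56 replicate 1, BC56_salt replicate 2 or BC56_salt replicate 3. The other 27 lists did not pass (camera adjusted p = 0.0638 to 0.931), ribosomal protein genes among them, with 11 positive, 13 negative and 139 not passing of 163, or 9 and 9 adjusted over the list alone (adjusted p = 0.837).

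**Figure D2:**
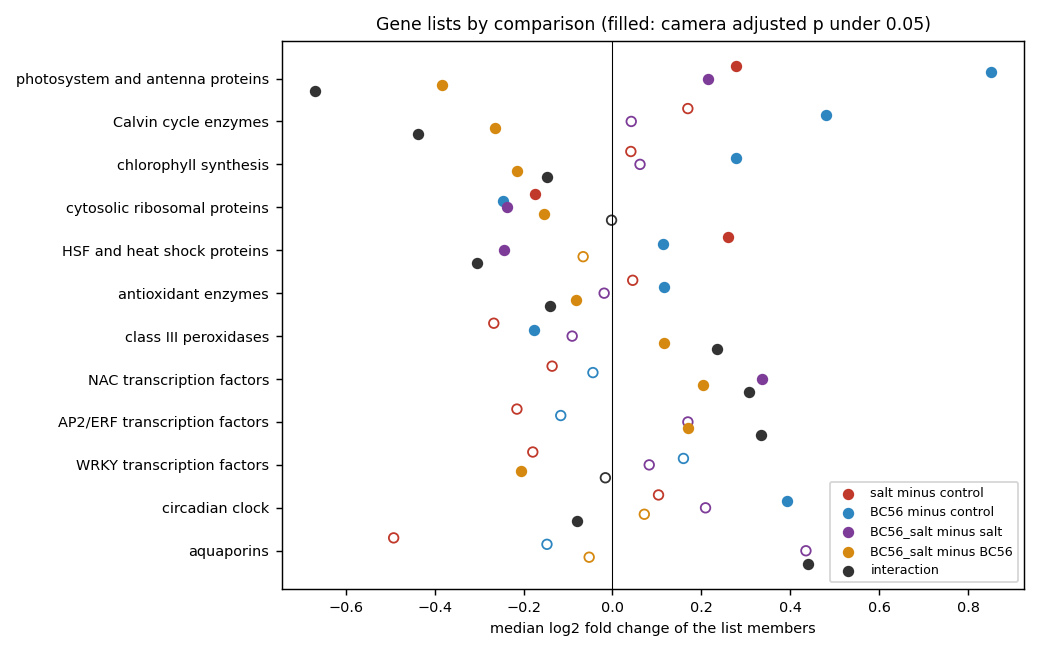
Median log2 fold change of the members (x axis) of 12 gene lists (y axis) in the 5 comparisons, in colour; filled circles passed the camera test at a preset correlation of 0.01 (adjusted p under 0.05), open circles did not. Photosystem and antenna genes stood at 0.85 in BC56 minus control and at -0.67 in the interaction, and ribosomal protein genes were below 0 in each comparison between a pair of groups.

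Over the 9445 genes that salt changed without BC56, the change from salt to BC56_salt had the opposite sign in 73.8%, against 56.2% (54.8% to 57.0% over 20 simulations) with no effect of BC56 under salt, since both comparisons use the salt libraries. Of these genes, 4400 were called in the opposite and 1105 in the same direction, against 1619 to 1703 and 3403 to 3471 in 20 simulations with the same salt effect in both backgrounds. Among all genes called in both, 2290 fell with salt and rose from salt to BC56_salt, and 2110 rose and then fell, whereas 539 rose and 566 fell in both. Across all 18529 genes tested, the covariance of these fold changes was -0.329 against a simulated -0.0563, and Pearson's r -0.582 against -0.192. Genes are not independent replicates. Over the 9445 genes again, BC56_salt minus BC56 was set against salt minus control, which share no library. The slope through 0 was 0.241, with r = 0.452 and the same sign in 72.6% of genes. Simulations with the same salt effect in both backgrounds gave slopes of 0.826 to 0.864 and the same sign in 98.5%. In these comparisons 1836 genes rose in both and 1816 fell in both, where independent lists would share 824 and 776, and 444 rose without BC56 and fell with it, against 836. Asparagine synthetase (LOC101214250), beta-galactosidase-like (LOC101210653), CPRF2-like (LOC101216137; interaction 3.23 ± 0.05) and the RING and CHY zinc finger gene LOC101221553 (3.18 ± 0.09) were among the genes that salt lowered and BC56 raised under salt. The effects of BC56 with and without salt, which share no library either, had 1799 genes up in both and 1545 down in both, against 865 and 714 for independent lists.

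**Figure D3:**
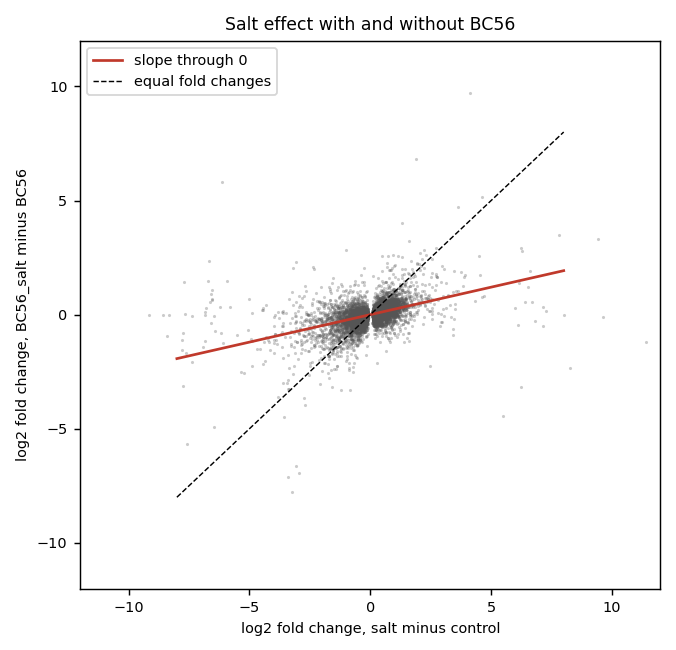
Log2 fold change of salt in plants with BC56 (y axis, BC56_salt minus BC56) against that without BC56 (x axis, salt minus control), each point 1 of the 9445 genes called in salt minus control. The solid line has the slope through 0 of 0.241 and is flatter than the dashed line, which marks equal changes.

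Further genes with an interaction were outside the lists that passed. Protein phosphatase 2C 24 (LOC101206871), of a family that damps abscisic acid signalling, stood at 59.9 ± 1.80 FPKM in control, 20.1 ± 0.922 in salt, 24.9 ± 1.68 in BC56 and 66.5 ± 3.41 in BC56_salt (2.94 ± 0.08). Potassium transporter 1 (LOC101222845) had 1.82 ± 0.10, trans-cinnamate 4-monooxygenase (LOC101221846) 1.67 ± 0.06, a pectinesterase (LOC101212388) 1.75 ± 0.08, MYB48 (LOC101211775) 1.19 ± 0.10 and the histone H1-like gene LOC101205659 1.10 ± 0.05. Negative interactions were those of PP2-B12 (LOC101220101; -3.72 ± 0.20), ammonium transporter 1 member 2-like (LOC101217871; -3.14 ± 0.20), MYB108-like (LOC101206042; -2.71 ± 0.31), a glutathione transferase (LOC101207634; -1.34 ± 0.09), ACC oxidase 5 (LOC101204347; -1.21 ± 0.05), inositol-3-phosphate synthase-like (LOC101207441; -0.93 ± 0.05) and pheophytinase (LOC101207761; -0.61 ± 0.06). The sequences of family members such as the HSP70 pair, the antenna genes and the lipoxygenases on chromosome 4 were not compared, and how reads that match more than 1 gene were counted is not given in the sources used here, so their single values are less certain.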

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

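Of the tests below, those of scaling, mesophyll share and harvest time for the photosystem genes and that of scaling for the ribosomal genes were chosen after the result was seen. The first results of this part were singled out by a test of the difference itself, the interaction: the effect of salt differed with BC56 in 5963 genes. Other splits exchanged BC56 labels within a salt level, and not all were drawn. In the 99 drawn, at most 2501 genes were called, and 14 called more than 1000. Of 100 splits, 1, the real one, gave as many as 5963. A split that mixes libraries with and without BC56 in a group widens the spread within groups and so lowers the count. The splits therefore cannot exclude a random grouping. The comparisons of 3 libraries against 3 have 10 splits each, too few for a share under 0.05: the real ones gave 9445 (salt minus control), 7461 (BC56 minus control), 7834 (BC56_salt minus salt) and 6277 genes (BC56_salt minus BC56), each 1 split of 10, and the highest of the others 0. These others mix the groups too, so their counts do not exclude a random grouping either.

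Positive interactions (log2 ± SE) were those of asparagine synthetase (LOC101214250, 4.97 ± 0.17), inactive beta-amylase 4 (LOC101210545, 3.67 ± 0.23), beta-galactosidase-like (LOC101210653, 3.53 ± 0.06), CPRF2-like (LOC101216137, 3.23 ± 0.05), a RING and CHY zinc finger gene (LOC101221553, 3.18 ± 0.09), protein phosphatase 2C 24 (LOC101206871, 2.94 ± 0.08), peroxidase 21-like (LOC101215428, 2.08 ± 0.08) and NAC72-like (LOC101202813, 1.96 ± 0.07). Smaller positive values belonged to aquaporin (PIP1-3, 1.902 ± 0.075), potassium transporter 1 (LOC101222845, 1.82 ± 0.10), pectinesterase-like (LOC101212388, 1.75 ± 0.08), IAA11 (LOC101204327, 1.69 ± 0.12), trans-cinnamate 4-monooxygenase (LOC101221846, 1.67 ± 0.06), MYB48 (LOC101211775, 1.19 ± 0.10) and histone H1-like (LOC101205659, 1.10 ± 0.05). Negative interactions were those of PP2-B12 (LOC101220101, -3.72 ± 0.20), HSP70 (LOC101210925, -3.32 ± 0.06), HSP70 (LOC101215599, -3.24 ± 0.05), ammonium transporter 1 member 2-like (LOC101217871, -3.14 ± 0.20), MYB108-like (LOC101206042, -2.71 ± 0.31), RAV2-like (LOC101203784, -2.59 ± 0.05) and APRR7 (LOC101222491, -1.72 ± 0.07). Smaller negative values belonged to LHCII type I (LOC101221671, -1.47 ± 0.04), glutathione transferase (LOC101207634, -1.34 ± 0.09), ACC oxidase 5 (LOC101204347, -1.21 ± 0.05), inositol-3-phosphate synthase-like (LOC101207441, -0.93 ± 0.05), protochlorophyllide reductase (NPR, -0.87 ± 0.04), CDSP32 (LOC101214005, -0.72 ± 0.05), sedoheptulose bisphosphatase (SBPASE, -0.68 ± 0.04) and pheophytinase (LOC101207761, -0.61 ± 0.06). The lists that passed had median interactions of -0.67 (photosystem and antenna), -0.44 (Calvin cycle), -0.31 (heat shock), -0.15 (chlorophyll synthesis), -0.14 (antioxidant), -0.0790 (clock), 0.21 (auxin), 0.23 (class III peroxidases; 0.03 without control replicate 1), 0.31 (NAC), 0.33 (AP2/ERF) and 0.44 (aquaporins). Of these 11 calls, 10 were lost with an estimated correlation and that of heat shock genes was kept; the clock call was lost in 11 of 23 alternatives, the auxin and aquaporin calls in 6 each, the NAC call in 4 and the antioxidant call in 1.

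The rise of photosystem and antenna genes in BC56 (median 0.85, 41 of 41 called) was set against 4 technical or tissue explanations. Scaling between libraries is argued against, since the lowest list median under 3 other scalings was 0.64. A rise of highly expressed genes in general is argued against too. The list median lay at percentile 100 of 10000 random lists matched on FPKM. With both tails left out, the medians of these random lists ran from -0.14 to 0.25. A larger share of mesophyll cells cannot be told apart from a rise within cells: the phloem list had a median of 0.24 and not a negative one, but its call is lost with an estimated correlation (adjusted p = 0.142) and 14 of its 25 members are F-box proteins, among them PP2-B12 (LOC101220101) with 62.7 FPKM in control and 272 in BC56; of the other 11 members, 5 rose and 0 fell. A different time of harvest stays open as well, because the labels give no time; dawn clock genes (7) had a median of 0.72 and evening genes (3) one of 0.25, the lower of the pair, so the signs were not opposite. BC56 itself, the biological difference that the design names, stays open and was not separated from these.

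Ribosomal protein genes were lower in BC56 minus control (median -0.25) and in BC56_salt minus salt (-0.24). A general fall of short transcripts is argued against. The list median lay at percentile 0 of random lists matched on transcript length and FPKM in both comparisons. With both tails left out, the medians of the random lists ran from -0.07 to 0.10 and from -0.12 to -0.00473. Scaling is argued against too, as the highest list median under 3 other scalings was -0.24. Both tests compared this list with other genes, and the list was lost with an estimated correlation (0.225 and 0.422), so that an effect of BC56 is a hypothesis that stays open.

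Fold changes under salt were smaller in BC56 plants over the genes that salt changed without BC56. Selection of genes on the comparison without BC56 is argued against as the whole cause: the slope was 0.241, below the simulated range of 0.826 to 0.864. A single library is argued against too, since the highest slope over the 12 fits without 1 library was 0.240. The pattern may reflect a weaker response to salt with BC56, or less salt reaching the leaf. Ion contents are not given in the sources used here and these were not told apart. Salt alone and BC56 alone also moved many of the same genes: 1982 rose and 1614 fell in both, against 1070 and 838 for independent lists. Another 578 and 935 moved in opposite directions, against 903 and 993. Both comparisons use the control libraries, which pushes the signs together by chance. How far this overlap lowers the slope was not tested.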

How the results depend on the processing

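All settings here were planned except counts divided by 4 and limma on log2(FPKM + 1) as a setting beside edgeR, which were chosen after seeing the data. That limma fit itself was the test planned for a table without raw read counts. Over the settings, 124 of 129 counts of changed genes stayed within 1.5 times the reported count, as did 112 of 119 counts of lists called. Of the list values, 4346 kept their side of the threshold, 77 passed newly and 89 no longer passed. A reversed camera direction was looked for only where the main fit or the alternative called the list, and 0 were found. The direction of lists called in neither was not checked. Of the values of named genes 3705 kept their call and 5 lost it, all of the miraculin-like gene LOC101213024, whose call ended without control replicate 1.

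With a log2 change of at least 1, the counts were 1413 (salt minus control), 709 (BC56 minus control), 877 (BC56_salt minus salt), 628 (BC56_salt minus BC56) and 984 (interaction), since the threshold removes smaller changes. Lists called in BC56_salt minus salt numbered 6, but 11 in limma with pseudocounts of 0.1, 5 and 1 and without trend, and 10 at a mean FPKM of at least 5; in the interaction they numbered 11, but 7 with quantile normalization (the cause was not tested). Without 1 library, lists called were 4 to 7 in salt minus control (7 without salt replicate 1), 10 to 12 in BC56 minus control, 5 to 9 in BC56_salt minus salt, 9 to 12 in BC56_salt minus BC56 and 9 to 13 in the interaction. Genes called without 1 library were 8559 to 9456, 6567 to 7584, 6919 to 7791, 5346 to 6288 and 5382 to 5734 in the same order.

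Medians of called lists moved by more than 1.5 times in places. In limma with a pseudocount of 5, that of heat shock genes in salt minus control was 0.15. In BC56 minus control it was 0.03 for heat shock, 0.03 for jasmonate, 0.17 for clock, 0.17 for chlorophyll synthesis, 0.12 for phloem and 0.25 for osmolyte genes, and for cell cycle genes -0.13 with a pseudocount of 0.1. In BC56_salt minus salt a pseudocount of 5 gave -0.16 for heat shock, 0.12 for NAC, 0.05 for phloem and -0.08 for glutathione transferase genes. In BC56_salt minus BC56 it gave -0.05 for WRKY, -0.03 for antioxidant and -0.14 for chlorophyll synthesis genes, and quantile normalization -0.07 for ribosomal protein genes. In the interaction it gave 0.17 for AP2/ERF, 0.14 for NAC, -0.18 for heat shock, -0.08 for chlorophyll synthesis, 0.27 for aquaporin and -0.02 for clock genes, and quantile normalization -0.44 for photosystem and -0.07 for antioxidant genes. Antioxidant genes in BC56 minus control were at 0.03 with quantile normalization and nearer 0 in the other limma fits. Without 1 library, the median was -0.12 for ethylene genes in salt minus control (control replicate 1), -0.08 for cell cycle genes in BC56 minus control (BC56 replicate 2) and 0.08 for NAC genes in BC56_salt minus BC56 (BC56 replicate 1). In BC56_salt minus salt it was 0.22 for NAC genes (BC56_salt replicate 2), -0.10 for glutathione transferases (BC56_salt replicate 3), and 0.16 and 0.44 for phloem genes (salt replicate 1, BC56_salt replicate 1). In the interaction it was 0.47 for NAC genes (BC56 replicate 3; 0.47 with no filter), 0.14 for auxin genes (BC56_salt replicate 1), and -0.14 for clock genes (BC56_salt replicate 2). In BC56 minus control the median of all genes tested was -0.0653 in limma with a pseudocount of 5 and -0.109 with 0.1, against -0.00338 in the main fit. In BC56_salt minus salt it was -0.0418 with a pseudocount of 5, against -0.00716. List medians in those fits therefore include a shift of all genes. Other causes of these moves of medians were not tested.

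The percentage of opposite signs, 73.8, was 73.1, 73.0 and 73.0 in limma with pseudocounts of 0.1, 5 and 1, 70.6 at a mean FPKM of at least 5, 72.8 on counts divided by 4, and 73.0 to 75.4 without 1 library. The slope between the salt effects, 0.241, was 0.312, 0.3005 and 0.311 in limma with pseudocounts of 0.1, 5 and 1, 0.313 without trend, 0.311 with quantile normalization, 0.309 at a mean FPKM of at least 5, 0.199 with no filter, 0.303 on counts divided by 4, 0.279 with only the groups of a comparison, 0.202 in DESeq2, and 0.197 to 0.240 without 1 library. The causes of these moves were not tested, and each slope lay below the simulated 0.826. With the replicate number as a block, 9237, 7250, 7614, 6021 and 5720 genes were called; the block ended the jasmonate call in BC56 minus control (adjusted p = 0.0551) and brought in the cell wall list in the interaction (0.0499), and it changed no other call of a list or named gene. A fit with only the groups of the comparison is the same fit for the interaction, so it has no value there. Depth limits genes of low counts: in simulated data for salt minus control, 9 of 27 genes with under 400 counts and a log2 change of 1 were recovered.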

Other observations

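The KEGG pathways of this part (116 tested) were added after the results above were seen, and the genes of the hypothesis below were chosen after their values were seen, whereas its tests were written before the list was measured. Proteasome genes, whose products break down tagged proteins, fell in 42 of 49 members and rose in 0 in BC56 minus control (median -0.27, camera adjusted p = 2.17e-12, adjusted p = 0.0216 with an estimated correlation). In salt minus control, 38 fell and 1 rose (median -0.23, camera adjusted p = 7.73e-05, adjusted p = 0.371 with an estimated correlation), and in BC56_salt minus salt 30 fell and 1 rose (median -0.16, camera adjusted p = 0.00225, adjusted p = 0.441 with an estimated correlation). Genes of protein processing in the endoplasmic reticulum (160) fell in 60 and rose in 14 in BC56_salt minus salt (median -0.12, camera adjusted p = 3.77e-05, adjusted p = 0.0261 with an estimated correlation). Citrate cycle genes (40) fell in 26 and rose in 4 in BC56 minus control (median -0.16, camera adjusted p = 3.22e-04, adjusted p = 0.142 with an estimated correlation). Beta-alanine metabolism genes (41) rose in 16 and fell in 2 in BC56_salt minus BC56 (median 0.13, camera adjusted p = 2.14e-04, adjusted p = 0.436 with an estimated correlation).

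Asparagine synthetase (LOC101214250), beta-galactosidase-like (LOC101210653) and proline dehydrogenase (LOC101219166; 13.4 FPKM in control, 3.46 in salt, 31.6 in BC56 and 13.6 in BC56_salt) were at their lowest in salt. Genes of these families are known from leaves kept in the dark or short of sugar, so a hypothesis was that salt lowered, and BC56 under salt raised, such a programme, which would include the breakdown of branched-chain amino acids. In salt minus control the 29 genes of that breakdown had a median of -0.16, with 11 fallen and 5 risen (p = 0.00425, camera with an estimated correlation). In BC56_salt minus salt the median was 0.03, with 10 risen and 8 fallen (camera p = 0.0237 with an estimated correlation), so that the condition set in advance was met with a median close to 0. Both comparisons use the libraries of salt alone, which pushes their signs apart by chance. No value without an effect of BC56 was simulated for this list, so the rise is not separate support. Isovaleryl-CoA dehydrogenase (LOC101216988) had -1.50 ± 0.05 and 0.86 ± 0.05 in these comparisons, methylcrotonoyl-CoA carboxylase subunit alpha (LOC101221786) -1.41 ± 0.04 and 0.68 ± 0.04, and a subunit of the branched-chain keto acid dehydrogenase (LOC101206829) -1.18 ± 0.05 and 1.27 ± 0.05. The estimated correlations were below 0 (-0.0183 in BC56_salt minus salt and -0.0171 in salt minus control). As run, the test takes such values as 0, so these unadjusted p-values hold no allowance for correlation between the genes. The interaction was positive in 11 and negative in 2 (median 0.14, camera p = 0.00101 with an estimated correlation). In BC56_salt minus BC56, which does not use the libraries of salt alone, 6 rose and 5 fell (median 0.06, camera p = 0.277 with an estimated correlation). The list also fell in BC56 minus control (median -0.14, 12 fallen and 4 risen, camera p = 0.0183 with an estimated correlation), which the hypothesis did not foresee. A lower sugar starvation response in salt alone may therefore be part of the pattern, but sugars were not measured in the data used here and the support in BC56_salt minus salt is weak.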
